A study of Oryza sativa Japonica Group with 8 samples.

How the data were processed

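Poly(A) RNA of the japonica subspecies of cultivated rice (Oryza sativa) was sequenced as 8 non-directional, paired-end libraries of 100 cycles on an Illumina HiSeq instrument, per the labels' protocols. The libraries came from flower buds, from flowers on the day of flowering, from flag leaves and roots taken at a before- and an after-flowering stage, from grains at the milk stage and from mature seeds. Each group held 1 library. Per the labels' protocols, the before-flowering material pooled stages from panicle initiation to the day before flowering, and the after-flowering material pooled later stages, so each of those libraries is an average over time. Non-directional libraries do not record the strand, so reads of overlapping loci on opposite strands cannot be told apart.

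The deposited table held 1 FPKM value (fragments per kilobase of transcript, scaled to the number of mapped fragments) per locus and library, computed by the authors. TopHat, Cufflinks and Cuffdiff are named in the submitters' processing notes; their versions, settings and order are not given in the sources used here. Positions are on the coordinates of the MSU Rice Genome Annotation Project Release 7, per the file headers. The table held 31187 loci with assembly identifiers and no gene names. The lowest row maximum was 1.00001 FPKM, so every locus had a value above 1 FPKM in at least 1 library, and loci below that level in all libraries are not analysed here. Of the loci, 20892 had a position of their own. The other 10295 (33.0%) shared a position with up to 45 loci in all, so a shared position is a span that holds the locus and not its own limits.

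Before the data were examined, 20 gene lists with 307 entries, 20 keyword lists and a rule for naming genes were fixed, together with the size rules and alternatives below. None could be applied by name. The identifiers of 0 loci matched the RefSeq gene table at hand, which follows another assembly (ASM3414082v1), and coordinates were not carried between assemblies. The gene lists, the keyword lists and the shares of expression they take are therefore not reported. Substitutes were chosen after the data were seen. Groups of loci were defined by organ. Shares of summed FPKM were given for the most abundant loci and for organ groups. For each stage comparison, the 2 loci with the highest and the 2 with the lowest ratio were named, among loci with at least 20 FPKM in the higher library and a value above 0 in both. For each organ, 1 locus was named, the one with a position of its own, at least 50 FPKM and the highest ratio to the other organs.

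With 1 library per group there is no estimate of replicate error, so no p-value was computed, and each comparison is between those libraries rather than between stages or organs. A locus was counted as different between 2 libraries when log2((FPKM + 1)/(FPKM + 1)) was at least 2 in size, that is 4-fold, and the higher library had at least 5 FPKM. All log2 ratios below are on this scale, which understates the change of low loci. A locus was counted as organ-enriched when the higher library of an organ had at least 10 FPKM and at least 5 times the highest value of the other libraries, both with 1 FPKM added. The 2 libraries of an organ are stages, not replicates. To follow the loci of 1 organ through a stage comparison of another, organ groups were defined again without the 2 libraries compared and without the library labelled roots after flowering. The median log2 ratio of each group was set against 10000 random lists of the same size, matched on mean expression in the 2 libraries over 20 bins. Intervals of these medians are 95% binomial intervals over loci, which are not replicates. Other intervals of shares are 95% Wilson intervals.

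The depth of the libraries is unknown. At low values no common step was found that would give whole reads: among 3092 loci below 0.15 FPKM in both leaves after flowering and the library labelled roots after flowering, the fullest bin of ratios, 0.02 wide on the log2 scale, held 2.13%. The precision of single values, and the smallest level that could be detected, can therefore not be given. Exact zeros in the table were found at loci with over 1000 FPKM in other libraries, so a zero is reported as "listed at 0" and no fold is given for it.

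The rules were tested on simulated data. In tables built from the 31187 loci with 100 loci changed 8-fold and 100 changed 3-fold, the 4-fold rule found 99 of the 8-fold loci for flowers against buds, 100 for leaves, 100 for roots and 99 for seeds. It called 4, 5, 4 and 5 of the 3-fold loci. The noise in these tables, an SD of 0.3 on the log2 scale, was assumed, since no replicates give it, so the simulation checks the computation and gives no rate of false calls. Alternatives were another pseudocount, filter, fold and scaling (median of ratios over the 13228 loci with at least 1 FPKM in every library, upper quartile, and equal sums over all loci or over all but the top 100). Added after the data were seen were counts without loci listed at 0 and organ counts without the library labelled roots after flowering. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.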

Results

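Gene expression was profiled in 8 rice libraries that follow the flower (buds, open flowers), the leaf and the root (each before and after flowering) and the grain (milk stage, mature seed). The table held 31187 loci, of which 13228 (42.4%) had at least 1 FPKM in all 8 libraries. The number of loci with at least 1 FPKM was 23910 in flower buds, 23754 in flowers, 20828 in leaves before flowering, 20435 in leaves after flowering, 20976 in roots before flowering, 20534 in the library labelled roots after flowering, 18103 in milk grains and 21940 in mature seeds. Milk grains thus had the fewest expressed loci of the 8 libraries, and their 100 most abundant loci took 37.7% of the summed FPKM. The share of the 100 most abundant loci was 29.3% in mature seeds, 24.0% in leaves before flowering and 17.8% in flower buds, the lowest of the 8. The summed FPKM lay between 569819 and 611306, and the read depth is unknown. There was 1 library per group, so none of the values has a replicate error.

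The first question was how the organs differ. Flower buds and flowers were close to each other, with a Pearson r of 0.961 across loci on the log2 scale. Leaves before and after flowering had r = 0.925. Milk grains and mature seeds had r = 0.741, and mature seeds had r = 0.736 with flower buds and 0.742 with flowers. Roots before flowering had r between 0.533 and 0.661 with the other 7 libraries. Milk grains had r between 0.533 and 0.571 with the 6 libraries other than mature seeds, and differed from them by at least 4-fold at 5877 to 6093 loci. These coefficients are across loci, which are not independent replicates.

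**Figure D1:**
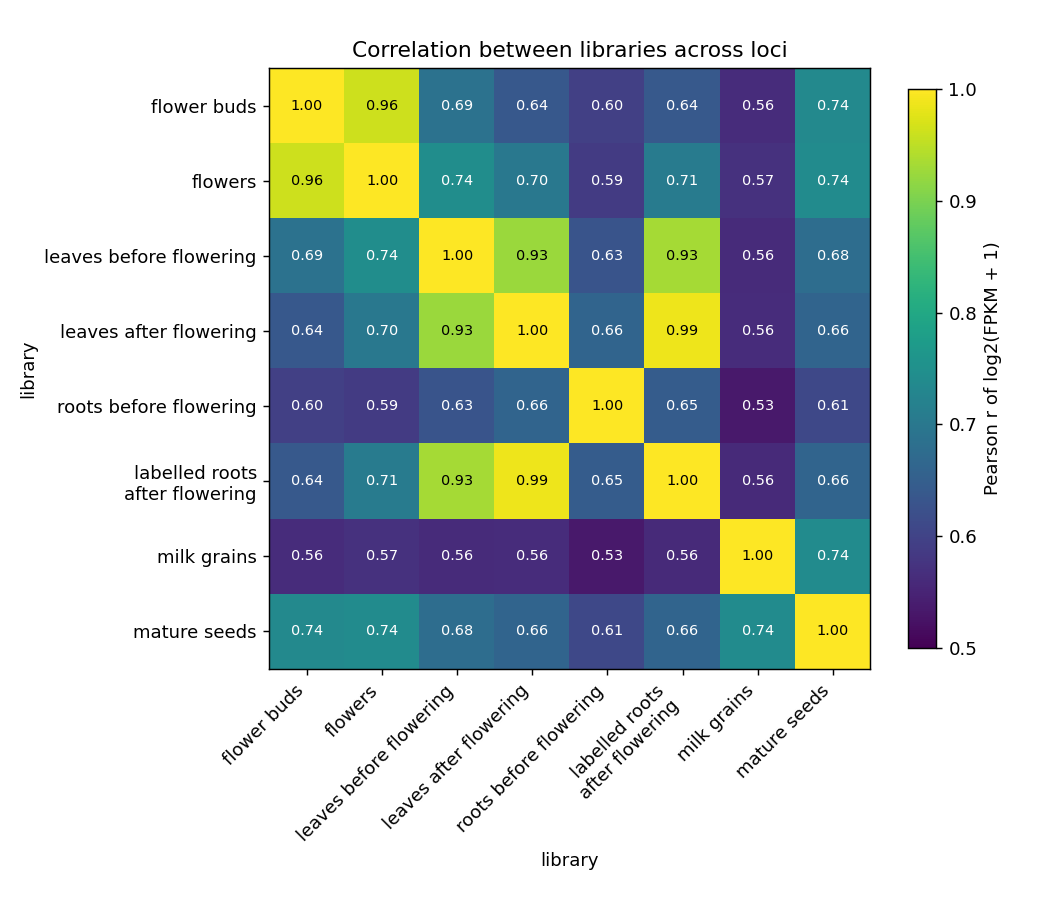
Pearson r of log2(FPKM + 1) across 31187 loci for each pair of the 8 libraries, 1 library per group. The library labelled roots after flowering has r = 0.987 with leaves after flowering and r = 0.646 with roots before flowering.

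The library labelled roots after flowering had the profile of a leaf library. It differed by at least 4-fold from leaves after flowering at 44 loci, and from roots before flowering at 4887. The 2 leaf libraries differed from each other at 943 loci. The 544 leaf-enriched loci, chosen without this library, had a median of 36.4 FPKM in it, against 39.4 in leaves after flowering, 20.02 in leaves before flowering and 1.12 in roots before flowering. Of these loci, 479 (88.1%) were within 2-fold of leaves after flowering. The 1285 loci that were enriched in roots before flowering over the flower and seed libraries had a median of 48.1 FPKM there. Their median was 1.97 FPKM in the library labelled roots after flowering, 2.46 in leaves after flowering and 1.63 in leaves before flowering. Every value drawn from the library labelled roots after flowering is subject to this, and organ groups are therefore given without it.

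Across the other 7 libraries, 769 loci were enriched in the flower, 544 in the leaf, 918 in the root and 921 in the seed. With the eighth library included, the counts were 766, 46, 919 and 909, so that the leaf count depended on it. Seed-enriched loci, chosen for being high there, took 43.5% of the summed FPKM in milk grains and 27.3% in mature seeds. They took 1.13% in flower buds and between 0.532% and 0.936% in the other 5 libraries. Root-enriched loci took 23.7% of the summed FPKM in roots before flowering and between 0.455% and 0.988% in the other 7 libraries. Flower-enriched loci took 12.4% in buds and 10.4% in flowers, and leaf-enriched loci took 12.0% in leaves before and 13.9% in leaves after flowering.

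**Figure D2:**
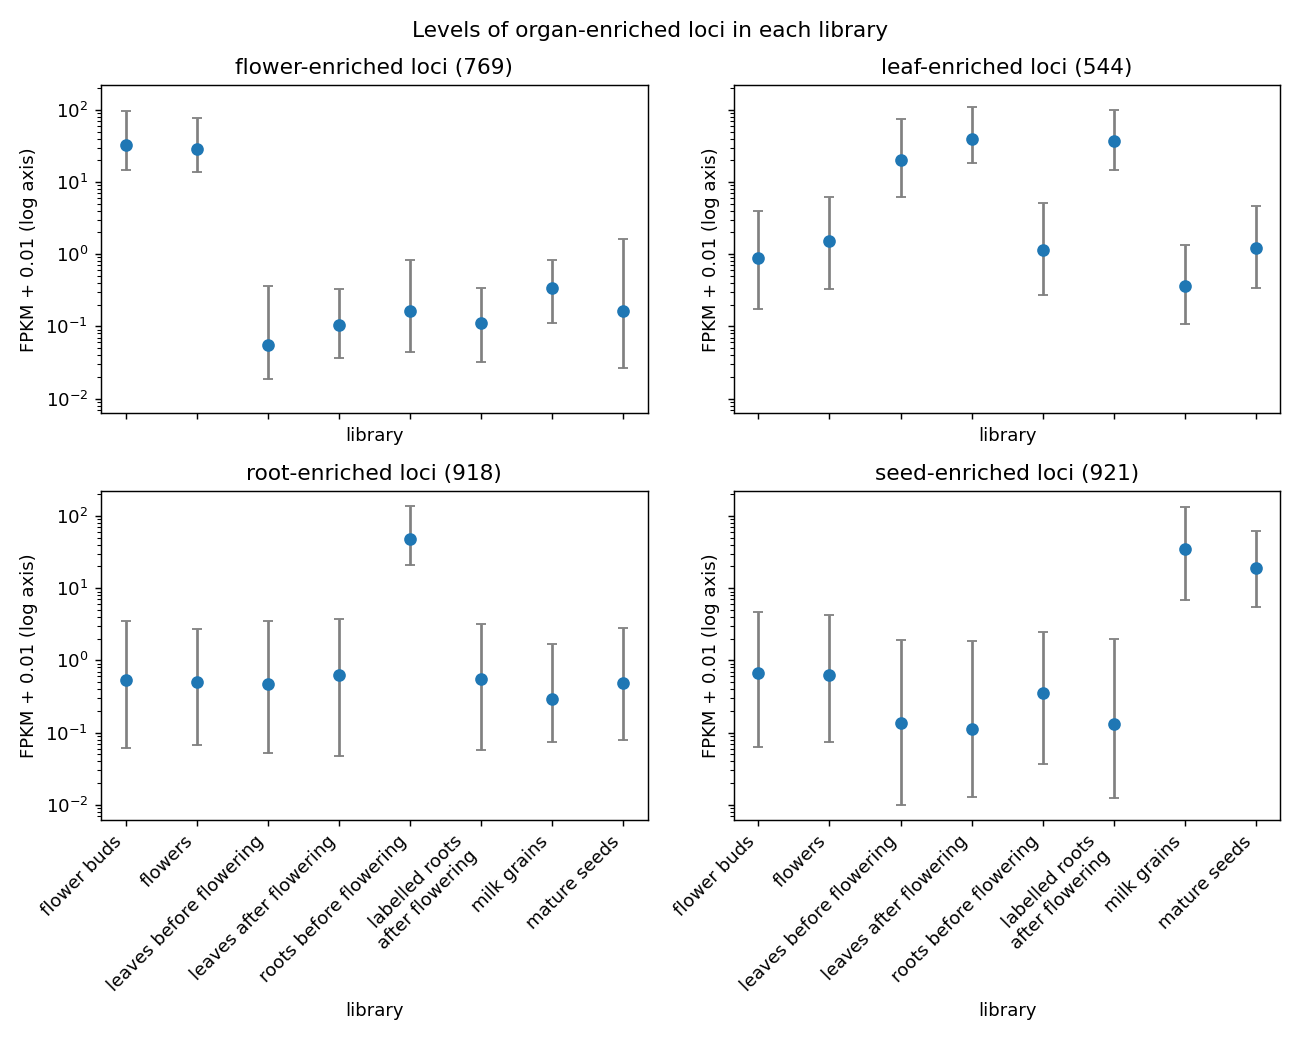
Median FPKM (points) and 25th to 75th percentile over loci (bars) of the 4 organ-enriched groups in each of the 8 libraries, on a log axis with 0.01 FPKM added; the groups were defined without the library labelled roots after flowering. In that library leaf-enriched loci had a median of 36.4 FPKM and root-enriched loci 0.543 FPKM.

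The locus with the highest ratio to the other organs is named for each organ, as the extreme of its group. The seed locus with the highest ratio lay on chromosome 7 (XLOC_055807, 6613130 to 6613762), with 8606 FPKM in milk grains and 9554 in mature seeds. It had 0.284 FPKM in roots before flowering and lower values, or a listed 0, elsewhere. The root locus lay on chromosome 9 (XLOC_066808, 22699919 to 22700959), with 591 FPKM in roots before flowering and 0.616 in milk grains, the highest of the other 7 libraries. The flower locus lay on chromosome 3 (XLOC_031185, 32425604 to 32426804), with 496 FPKM in buds, 184 in flowers and 0.755 in milk grains. The leaf locus lay on chromosome 1 (XLOC_003377, 42958522 to 42965010), with 349.9 FPKM in leaves before and 1162 in leaves after flowering. It had 1016 FPKM in the library labelled roots after flowering and 0.813 in roots before flowering. Coordinates are those of MSU Release 7. The table pairs no locus with a gene name, an exon or a UTR.

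The second question was what differs between stages of the same organ. The number of loci at least 4-fold different was 187 from flower buds to flowers, 943 between leaves before and after flowering, 4887 between the libraries labelled roots, and 3856 from milk grains to mature seeds. These were 1.17%, 6.38%, 30.0% and 26.0% of the loci with at least 5 FPKM in either library.

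**Figure D3:**
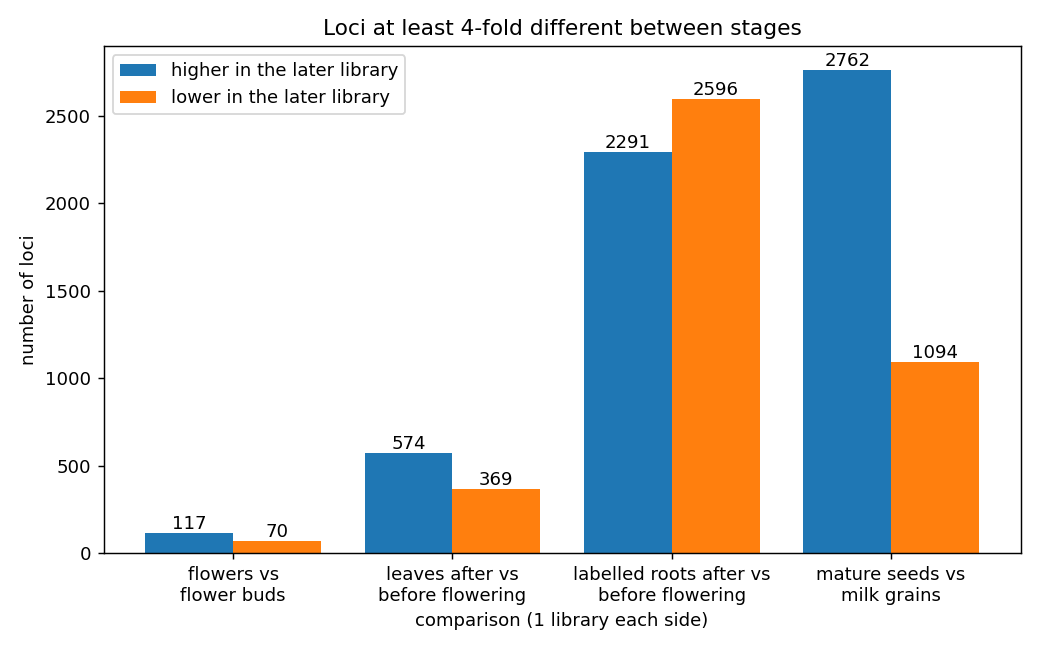
Number of loci at least 4-fold higher or lower in the later library (FPKM + 1, at least 5 FPKM in the higher library), 1 library on each side. The counts run from 117 higher and 70 lower for flowers to 2762 higher and 1094 lower for mature seeds; the pair labelled roots includes the leaf-like library.

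Open flowers differed little from buds. Of 16038 loci, 117 were at least 4-fold higher in flowers and 70 were lower. Of the 117 higher loci, 86 (73.5%) also had at least 5 FPKM in a leaf library, 73 (62.4%) in a seed library and 36 (30.8%) in roots before flowering. Over all 14988 loci with at least 5 FPKM in flowers, these shares were 80.2%, 80.3% and 67.9%. Of the 70 lower loci, 38 (54.3%) had at least 5 FPKM in roots before flowering and 30 (42.9%) in a leaf library, against 67.9% and 77.7% of all 14921 loci with at least 5 FPKM in buds. Loci enriched in leaves over root and seed were higher in flowers as a group: the median log2 ratio of 1319 loci was 0.37 (0.35 to 0.40), above all 10000 random lists, whose medians lay between -0.01 and 0.02 in 95% of draws. This median left its interval under each alternative. It was 0.334 after median-of-ratios scaling and 0.415 with equal sums over all loci. With a pseudocount of 0.1 it was 0.501, and among members with at least 5 FPKM 0.463. The median level of these 1319 loci was 6.73 FPKM in buds and 9.66 in flowers, and 29 of them passed the 4-fold rule upwards, 9 downwards and 1281 neither. Loci enriched in the root and in the seed had medians of -0.03 (1082 loci, 6 higher and 13 lower by the rule) and -0.01 (1345 loci, 9 higher and 7 lower). Both medians lay below all 10000 random lists and close to 0, and among members with at least 5 FPKM they were -0.45 and -0.16. Here and in the other comparisons this limit is on the higher of the libraries compared, so a change helps a locus to pass it and the median is enlarged in part by the choice. Of the 769 flower-enriched loci themselves, 9 were at least 4-fold higher in flowers, 20 were lower and 740 neither, in a group chosen on the higher of these libraries. A locus on chromosome 7 (XLOC_053276, 4143218 to 4146866) had 0.308 FPKM in buds and 39.97 in flowers, a log2 ratio of 4.97, and 28.5 FPKM in leaves before flowering. The other named locus (XLOC_054009) lies within a span shared by 8 loci (chromosome 7, 14118020 to 14304165) and had 0.0968 FPKM in buds, 41.9 in flowers and 810.5 in roots before flowering. The 2 loci furthest in the other direction were XLOC_053112 (chromosome 7, 2175127 to 2177640), with 55.3 FPKM in buds and 2.15 in flowers, and XLOC_043616 (chromosome 5, 24583249 to 24584945), with 267 and 22.9 FPKM. The first of these had 3672 FPKM in leaves before flowering. Of the 187 loci, 7 of the higher and 9 of the lower ones were listed at 0 in 1 of the libraries.

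Leaves after flowering had 574 loci at least 4-fold higher and 369 at least 4-fold lower than leaves before flowering, of 14789 loci. Of the higher loci, 170 (29.6%) had at least 5 FPKM in a flower library, against 85.7% of all 13305 loci with at least 5 FPKM in leaves after flowering. Of the lower loci, 286 (77.5%) did so, against 87.9% of all 13451 loci with at least 5 FPKM in leaves before flowering. The loci higher after flowering had at least 5 FPKM in roots before flowering in 319 cases (55.6%), and the lower loci in 164 cases (44.4%), where all such loci did so at 73.3% and 72.3%. In 195 cases (34.0%) the higher loci reached 5 FPKM in no other organ, and the lower ones in 54 (14.6%), against 7.25% and 6.57% of all such loci. Within the leaf-enriched group, 190 of 544 loci were at least 4-fold higher after flowering and 52 were lower; the group was chosen on the higher of the leaf libraries, so a difference between them helps a locus to enter it. Of 1285 root-enriched loci, 114 were at least 4-fold higher after flowering, 38 were lower and 1133 neither, with a median log2 ratio of 0.03 (0.01 to 0.07), above all 10000 random lists. Among members with at least 5 FPKM the median was 0.70. Among flower-enriched loci, 4 of 990 were at least 4-fold higher and 39 were lower, with a group median of 0.01 (0 to 0.01) that differs in sign from these counts. The median level of that group was 0.1503 FPKM before and 0.188 after flowering. Among its members with at least 5 FPKM the median was -1.27. Of 1004 seed-enriched loci, 16 were higher and 7 lower, with a median of 0. The named loci higher after flowering were XLOC_001875 (chromosome 1, 24392840 to 24393423), with 1.16 and 109 FPKM, and XLOC_015759, within a span shared by 2 loci (chromosome 11, 18426018 to 18445650), with 13.7 and 818 FPKM. The named loci lower after flowering were XLOC_052282 (chromosome 6, 8105183 to 8105787), with 268 and 0.0123 FPKM, and XLOC_018116 (chromosome 12, 10651864 to 10653450), with 98.0 and 0.206 FPKM. Of the called loci, 12 higher and 25 lower ones were listed at 0 in 1 leaf library.

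The pair labelled roots before and after flowering differed at 4887 loci, close to the 5112 between leaves and roots before flowering. Of 16269 loci, 2291 were at least 4-fold higher and 2596 lower in the later library. Of the 2291 higher loci, 2224 (97.1%) had at least 5 FPKM in a leaf library, as did 98.2% of all 13244 loci with at least 5 FPKM in the later library. Leaf-enriched loci had a median log2 ratio of 2.32 (2.04 to 2.57) over 913 loci, above all 10000 random lists, with 491 loci higher, 60 lower and 362 neither. Flower-enriched loci had 6 of 874 higher and 119 lower, and seed-enriched loci 21 of 1040 higher and 100 lower. Their medians were -0.04 and -0.05, and -3.02 and -0.87 among members with at least 5 FPKM. The named loci higher in the later library, XLOC_060864 (chromosome 8, 5806457 to 5808458) and XLOC_062013 (chromosome 8, 21171213 to 21172680), had 3.88 and 2.40 FPKM in roots before flowering and 3577 and 2476 FPKM in the later library. In leaves before flowering they had 3654 and 3245 FPKM. The named loci lower in the later library, XLOC_026511 (chromosome 2, 22509601 to 22510611) and XLOC_066173 (chromosome 9, 14479022 to 14479844), had 2082 and 2170.0 FPKM in roots before flowering and 0.193 and 1.32 FPKM in the later library. The median log2 ratio of all tested loci was 0.24 as deposited and -0.09 after median-of-ratios scaling, and the counts were then 1942 higher and 3132 lower. Whether these differences are a change of roots with flowering is not settled by these libraries.

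The third question was whether leaves and roots differ at the same loci after flowering. Of 13653 loci tested in both, 235 were at least 4-fold higher in both later libraries, where independent lists would share 86.3, and 101 were lower in both, where 14.6 would be shared. Another 53 loci were higher in leaves and lower in the pair labelled roots (31.4 for independent lists), and 73 were lower in leaves and higher in that pair (40.1). The correlation of the log2 ratios across loci, which are not independent replicates, was 0.0852. The 2 later libraries were close to each other (r = 0.987, 44 loci at least 4-fold different), so both ratios had nearly the same later values. Overlap in the same direction is in part built in by this. The numbers for independent lists are therefore no usable reference, and the opposite directions exceeded them as well. The later library of the pair labelled roots had a leaf-like profile, so whether these overlaps describe roots is not settled.

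Mature seeds differed widely from milk grains. Of 14826 loci, 2762 were at least 4-fold higher in mature seeds and 1094 were lower. Of the higher loci, 2198 (79.6%) had at least 5 FPKM in a flower library, 1642 (59.4%) in a leaf library and 1496 (54.2%) in roots before flowering, and 435 (15.7%) in none of these. Over all 13201 loci with at least 5 FPKM in mature seeds, the shares were higher for each organ, at 89.5%, 80.5% and 72.6%, and 7.24% for none. Loci lower in mature seeds were more often seen in the grain alone: 453 of 1094 (41.4%) reached 5 FPKM in no other organ, against 9.81% of all 10413 loci with at least 5 FPKM in milk grains. Among the 921 seed-enriched loci, 285 were at least 4-fold higher in mature seeds, 431 were lower and 205 were neither, in a group chosen likewise on the higher of the seed libraries. Leaf-enriched loci were higher in mature seeds as a group, with a median log2 ratio of 0.51 (0.41 to 0.59) over 608 loci, above all 10000 random lists, and with 84 higher and 18 lower. The random lists had a median of 0.27, so a part of this ratio was shared by loci of like expression. The median of the leaf-enriched loci was 0.406 after median-of-ratios scaling, just below its interval, and 0.65 with equal sums over all loci. It was 1.19 with a pseudocount of 0.1, and 1.79 among members with at least 5 FPKM. Flower-enriched loci had 266 of 1179 higher and 38 lower, with a median of 0.25 (0.15 to 0.40) at the 79.2 percentile of the random lists. The median of the flower-enriched loci was 0.15 after median-of-ratios scaling and 0.60 with a pseudocount of 0.1. It was 2.54 among members with at least 5 FPKM, a limit that selects in part for the change. Of 1049 root-enriched loci, 55 were higher, 59 lower and 935 neither. Their median of 0.01 (0 to 0.04) lay below all 10000 random lists, whose median was 0.15. The median of the root-enriched loci was -0.002 after median-of-ratios scaling and -0.38 among members with at least 5 FPKM. The named loci higher in mature seeds were XLOC_062440 (chromosome 8, 26725897 to 26728795), with 1.29 and 991 FPKM, and XLOC_047449 (chromosome 6, 2898783 to 2900617), with 0.959 and 627 FPKM. The named loci lower in mature seeds were XLOC_019721 (chromosome 12, 4411255 to 4415934), with 713 and 0.390 FPKM, and XLOC_003097 (chromosome 1, 39501329 to 39502978), with 516 and 0.0221 FPKM. The balance of directions depended on the scaling. The median log2 ratio was 0.43 as deposited, 0.14 after median-of-ratios scaling and 0.04 after upper-quartile scaling. With the upper quartile the counts were 2387 higher and 1694 lower, so that the share of higher loci was 58.5% in place of 71.6%.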

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

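The tests in this part were chosen after the results were seen. In all, 126 loci were at least 4-fold different after flowering in opposite directions in leaves and in the pair labelled roots, and the difference between the pairs was not tested, since each group held 1 library. The later library of the second pair is the leaf-like one.

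The first pattern weighed is that library itself, which had r = 0.987 with leaves after flowering. Roots mixed with leaf tissue or leaf RNA are argued against, for a root share of 5% or more and if roots after flowering still express these loci, because the 1285 root loci exceeded leaves after flowering by a median of -0.0422% (-0.0965 to -0.0166, quartiles -2.07 and 0.197) of their level in roots before flowering. A swap with a leaf library of this series is argued against, again only if roots after flowering still express these loci. At most 11.8% (10.2 to 13.7) of the root loci reached 50% of their root level in either leaf library. A leaf library under this label stays open as a candidate explanation: the 44 loci at least 4-fold different from leaves after flowering, against 943 between the 2 leaf libraries, do not exclude it, but restate the pattern and do not support it. A change of the root itself with flowering, which the design names, also stays open and was not tested; it would have to bring 479 of 544 leaf loci to within 2-fold of leaves after flowering, and root loci to a median of 3.42% of their level in roots before flowering.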

How the results depend on the processing

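Depth is unknown and groups hold 1 library, so what follows shows how counts move with the rules and not how they would repeat. No paired analysis was possible because each group held 1 library, so there were no replicate pairs. The share of summed FPKM without organelle and ribosomal RNA genes was not run, since no locus is named. Over the alternatives for the counts, 79 values stayed within 1.5 times and 53 did not; the cause was not tested beyond what each setting changes by construction. Over the alternatives for the medians of organ groups, 17 values stayed within the interval and 31 did not. No median whose interval excluded 0 changed sign. Of those whose interval reached 0, flower loci in leaves went from 0.01 to -1.27 among members with at least 5 FPKM, and root loci in mature seeds from 0.01 to -0.38 there and to -0.002 with median-of-ratios scaling. With a pseudocount of 5, the loci higher and lower numbered 35 and 26 for flowers, 243 and 145 for leaves, 1156 and 1377 for the pair labelled roots, and 1022 and 557 for mature seeds. With a 2-fold limit they numbered 722 and 765, 1724 and 1761, 4392 and 3981, and 5271 and 2592. With an 8-fold limit they numbered 23 and 13, 165 and 107, 1171 and 1535, and 1173 and 435. With at least 20 FPKM they numbered 64 and 44, 358 and 215, and 1337 and 1486, and 1241 loci were higher in mature seeds. For flowers, 106 loci were lower with a pseudocount of 0.1, and 186 were higher with equal sums over all but the top 100 loci. For mature seeds, 1694 were lower with upper-quartile scaling. Leaving out loci listed at exactly 0, added after the data were seen, kept every count of the 4 stage comparisons within 1.5 times. The organ counts that follow vary those over all 8 libraries (766 in flower, 46 in leaf, 919 in root and 909 in seed). At 2 times the other libraries they numbered 1443 in flower, 504 in leaf, 1740 in root and 1997 in seed. At 10 times they numbered 26 in leaf, 522 in root and 597 in seed, and with at least 50 FPKM 324 in flower, 449 in root and 526 in seed. Asking the lower library of each organ to pass gave 460 in flower, 0 in leaf, 0 in root and 187 in seed; the leaf and root values depend on the leaf-like library, which is counted here as a root as labelled. Leaving out the library labelled roots after flowering, added after the data were seen, gave 544 in leaf. Loci higher in both later libraries of leaves and roots numbered 149 with at least 20 FPKM and 811 with a 2-fold limit, and loci lower in both 53 and 377.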

Other observations

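The tests in this part were chosen after the results were seen. Organ-enriched loci were neighbours on the chromosomes more often than in random orders, although most had no such neighbour. The random orders were not matched on expression, while an enriched locus must reach 10 FPKM. The counts therefore do not separate an organ effect from a clustering of well-expressed loci. Among loci with a position of their own, 67 pairs of neighbours were both flower-enriched, out of 603 flower-enriched loci, where 1000 random orders gave 17.6 on average and 33 at most. The same count was 40 for 342 leaf loci (5.78 on average, 16 at most), 83 for 714 root loci (24.4 and 43) and 61 for 671 seed loci (21.5 and 37). The densest flower run within 200 kb held 15 flower-enriched loci among 15 loci in 86.5 kb (chromosome 9, 14258394 to 14344912), with medians of 432 FPKM in buds, 305 in flowers and at most 1.24 in the other 6 libraries. A seed run on chromosome 10 (9941277 to 10017346) held 9 seed-enriched loci among 13, with medians of 27.2 FPKM in mature seeds and 0.109 in milk grains. A root run on chromosome 7 (1319030 to 1433407) held 7 among 9, with a median of 17.5 FPKM in roots before flowering, and a leaf run on the same chromosome (1529239 to 1673471) held 6 among 16, with medians of 5.90 and 20.8 FPKM in leaves before and after flowering. Whether neighbours share reads through similar sequence was not tested, since no sequence was at hand. A position of its own does not keep a locus from overlapping its neighbour. Reads of overlapping loci on opposite strands cannot be told apart in these libraries. Whether such overlap adds to the counts of neighbours was not tested either.

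Mature seeds had 1484 loci at 5 FPKM or more that were listed below 1 FPKM in milk grains, 59 of them at 0. The count is on values as deposited. The median-of-ratios factor was 0.773 in milk grains and 0.963 in mature seeds, so the count depends on the scaling. Of the 1484 loci, 1035 (69.7%) had at least 5 FPKM in a flower library, 668 (45.01%) in a leaf library and 608 (41.0%) in roots before flowering. Over all 13201 loci with at least 5 FPKM in mature seeds, the shares were 89.5%, 80.5% and 72.6%. At the other end, 1372 loci stayed within 2-fold over all 8 libraries. Without the library labelled roots after flowering, enrichment in a single library was found at 918 loci in roots before flowering, the sole root library then, 399 in milk grains, 272 in mature seeds, 150 in leaves after flowering, 46 in leaves before flowering, 3 in flower buds and 1 in flowers. With that library included, leaves after flowering had 2.

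The second pattern weighed is abundant loci listed at exactly 0 in 1 library. Such a locus on chromosome 7 (20733145 to 20735347) had between 1189.8 and 1731 FPKM in 7 libraries and was listed at 0 in milk grains, and one on chromosome 1 (23607347 to 23608583) had 2270.1 FPKM in buds and was listed at 0 in flowers. Over the flower, leaf and seed pairs, without the pair labelled roots because its libraries differ like organs, 29 of 678 values (4.28%, 2.99 to 6.08) were exactly 0 where the partner library was above 500 FPKM, against 23 of 26283 (0.0875%, 0.0583 to 0.131) between 20 and 100 FPKM; in the pair labelled roots the shares were 2 of 242 (0.826%, 0.227 to 2.96) and 0.385% (0.276 to 0.538), with overlapping intervals. Loci silent at 1 stage are argued against as the general account, because in the 3 pairs 1 value lay above 0 and below 0.1 FPKM where the partner was above 500, beside the 29 zeros. Failed estimates at very abundant loci are a candidate explanation, consistent with the higher share of 4.28% above 500 FPKM in those 3 pairs, of which the seed pair gave 20 of the 29 zeros.

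The third pattern weighed is a near-constant trace of flower loci in milk grains. Over 81 loci with at least 200 FPKM in a flower library and at most 3% of it elsewhere, milk grains had a median of 0.310% of the flower level (middle of the loci 0.272% to 0.362%, a 1.33-fold range), and none was listed at 0. Expression by the grain itself at a level set locus by locus is argued against: of 82 loci chosen with no limit on milk grains, 12 (14.6%, 8.57 to 23.9) lay outside 2-fold of the median, and 1 was above 3%. One source of flower RNA or reads in the library is a candidate explanation that stays open, since it would keep loci in 1 ratio, but the 1.33-fold range is the pattern itself and no independent test of it. Pieces of floret left on the grains could give the same ratio over these flower loci. The flower loci alone cannot tell such pieces apart from reads carried over between libraries. The same loci had 0.0495% in the library labelled roots after flowering, 0.0488% in roots before flowering, 0.0509% in leaves after flowering, 0.0136% in mature seeds and 0.00913% in leaves before flowering.

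Leaf loci had a median of 0.213% of the leaf level in milk grains (32 loci, 0.175% to 0.278%), against 0.714% in mature seeds (0.181% to 1.73%). The medians of these leaf loci were 0.337% in roots before flowering, 0.233% in flowers and 0.0890% in flower buds. Root loci had a median of 0.204% of the root level in milk grains (50 loci, 0.104% to 0.346%), above their medians in the other 6 libraries, which lay between 0.0739% and 0.126%. In flower buds and flowers the root loci had medians of 0.126% and 0.106%. A small amount of floret would thus bring almost none of these leaf and root loci. Their levels in milk grains argue against floret pieces as the source of these loci. Whether they share a source with the flower loci was not tested.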
